A study of Mus musculus with 4 samples.

How the data were processed

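RNA was sequenced from DCs and CD3+ T cells of MC38 tumours in mice given PBS or X-Ray+O-IMDQ. The labels describe 4 libraries in 4 groups, 1 per group. RNA extraction, library construction and sequencing were by BGI according to the labels. The submitters' processing notes name HISAT2 2.0.4, RSEM 1.2.12, DESeq2 1.24.0, R 3.3.1 and genome build GRCm39, but which tool did which step is not given in the sources used here. The deposited tables, 1 per cell type, list 21959 genes with read counts, which are raw counts per gene in whole numbers. They also list FPKM, which the authors scaled to gene length and to the counted reads of each library, and a gene length in bases. It was checked that each FPKM value equals the count scaled by the listed length and the column total, within a relative difference of 2.04e-07. Of the listed genes, 51 have no symbol and 44 share a symbol with another listed gene.

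Libraries were matched to samples by the read file numbers in the sample descriptions. The titles number the PBS samples 2 while their descriptions carry number 1, and the treated DC sample is numbered 1 in its title and 4 in its description. The description was followed in each case. Each table holds 1 more PBS library that matches no sample, so these 2 libraries, with 4 columns, were not used here. Total counts were 23797357 for PBS DCs, 14056428 for treated DCs, 18649824 for PBS T cells and 18463944 for treated T cells. A count of 0 allows up to 3 counts, or 0.126, 0.213, 0.161 and 0.162 CPM in the same order.

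Counts were scaled within each cell type with TMM (edgeR 4.0.16 in R 4.3.3). For each gene the log2 ratio of treated over PBS was given with an exact conditional binomial (Clopper-Pearson) 95% interval. A library at 0 was set to 3 counts, and the fold at that floor stands for a bound, while the interval limit lies nearer 0. With 1 to 3 counts the ratio is given with its interval. A gene entered with at least 20 counts in either library and a symbol, and was called with a log2 ratio of at least 1 in size and an interval excluding 0. No tests with p-values were made, since 1 library per group leaves no replicate error.

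Before the data were examined, 22 programme lists and 20 marker lists were fixed with 554 genes, of which 542 are in the tables. The programme lists were type I interferon-stimulated genes, interferon-gamma-induced genes, NF-kB and TLR-induced inflammatory genes, endosomal TLR pathway, DC maturation, MHC class II and class I presentation, cytotoxic effectors, T cell activation, exhaustion, naive and memory genes, regulatory T cells, Th1, Th2, Th17, chemokines, proliferation, p53 response, glycolysis and hypoxia, oxidative phosphorylation, immediate-early and heat-shock genes, and immunosuppressive myeloid genes. The marker lists were T, CD8 T, CD4 T, gamma-delta T, NK, B, plasma, conventional DC, cDC1, cDC2, mature regulatory DC, plasmacytoid DC, macrophage, monocyte, neutrophil, mast, fibroblast, MC38 epithelial, endothelial and erythroid cells. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. It was called outside below percentile 2.5 or above 97.5, and lists with fewer than 5 measured members had no percentile. Members at 0 in 1 library entered at their bound. Intervals of list medians came from 10000 bootstrap draws of members.

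Named genes were fixed by a rule: the 15 highest and 15 lowest by the interval bound nearer 0, with at least 100 counts in the higher library, and without gene models, receptor segments, ribosomal protein and mitochondrial genes. To these were added the 2 to 4 most abundant members of each programme list, any such member at least 2-fold apart, and 14 genes fixed in advance. A gene outside this rule is named as chosen after its values were seen. Some genes that meet the rule are not reported here.

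Alternatives were total-count CPM, the deposited FPKM, DESeq2 1.42.0 size factors, upper-quartile scaling, minimum counts of 1 and 100, log2(CPM + 1), scaling without ribosomal, mitochondrial and receptor genes, 1.5-fold and 4-fold thresholds, list means and unmatched random lists. Chosen after seeing the data were centring on the median of all genes, at least 20 counts in both libraries, and a correction for gene length and GC content. GC content came from mouse transcripts of GENCODE M21 matched by gene identifier, for 99.9% of genes in each cell type. Planned use of comparison columns made by the authors could not be carried out, and such columns were not used here. The method was tested on simulated data: genes set 4-fold and 8-fold apart were recovered in 100% of cases, unchanged genes were called in 0.233% of cases for DCs and 0.227% for T cells, and lists with no shift lay outside in 4.50% and 5.50% of cases. The simulated counts held counting error only, and the simulated list members were independent of each other. These rates therefore do not show how often calls in the real libraries would be wrong. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.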

Results

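The series profiled RNA from dendritic cells (DCs) and from CD3+ T cells of MC38 tumours, a mouse colon carcinoma model. The mice received PBS or X-Ray+O-IMDQ, which the series calls a radiotherapy-activated prodrug, and cells were collected 72 h after the second treatment. The labels gave 4 libraries in 4 groups, with 1 library per group. The PBS DC library held 23797357 counts and the treated DC library 14056428. The PBS T cell library held 18649824 counts and the treated T cell library 18463944. The further PBS library of each table matched no sample and was not used here. With 1 labelled library per group there was no replicate check, so every comparison is between libraries and not between conditions, and no p-value is given. Ratios are of TMM-scaled counts with an exact conditional binomial 95% interval. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. A gene was called higher or lower when it was at least 2-fold apart and its interval excluded 0 on the log2 scale. Gene positions are those listed with the counts, for which the submitters' processing notes name genome build GRCm39.

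The comparison within DCs addresses how the treatment affected dendritic cells in the tumour. Type I interferon-stimulated genes, which carry out and regulate antiviral responses, were higher in the treated DC library, with a median ratio of 4.01-fold over 37 measured genes. Genes for MHC class II presentation, which displays peptides to CD4+ T cells, were lower, with a median 4.31-fold below the PBS library over 13 genes. Chemokine genes were higher by a median of 2.44-fold over 20 genes, led by Ccl6 and Ccl17. Genes of glycolysis and hypoxia were lower by a median of 2.10-fold over 22 genes. In the order given, these list calls held in 12, 11, 11 and 9 of 12 alternatives. Alternatives that changed only the scaling, among them the deposited FPKM, shift all genes alike, so no list percentile could change under them. Among 10316 genes that passed the count filter, 3112 were called higher and 4317 lower. Of the lower genes 1525 were at 0 in the treated library, and of the higher ones 387 were at 0 in the PBS library. Of 20 programme lists with enough members, 4 lay outside the range of random lists, where randomly drawn genes give 1. Members of a list can vary together, so more lists than this can lie outside by chance.

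Of the 37 interferon-stimulated genes, 25 were higher, 4 were lower and 8 were neither in the treated DC library. The list median lay at percentile 100 of random lists, with a bootstrap interval over members from 1.16 to 2.37 on the log2 scale. Irf7 (ENSMUSG00000025498, chromosome 7, 140842619 to 140846394), the transcription factor that amplifies type I interferon production, was 4.49-fold higher, from 50.3 to 226 CPM (counts scaled to library size). Rtp4 was 5.50-fold higher and Ifit3, an antiviral protein, was 4.56-fold higher. Mx1, a dynamin-like antiviral GTPase, had 0 counts in the PBS library and 779 in the treated one. At the floor of 3 counts it was 458-fold higher, with an interval from 371.7-fold upward. The 4 members lower in the treated library were Ifi35, Oas1a, Oas1g and Cmpk2, with log2 ratios of -1.66, -1.84, -3.03 and -1.61. The abundant member Zbp1, a sensor of Z-form nucleic acid, had a log2 ratio of -0.48 and Isg15, named after its values were seen, one of -0.89, and neither was called. Summed over the list, expression was 1305 CPM in the PBS library and 2812 CPM in the treated one.

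Of the 13 MHC class II genes, 10 were lower, 0 were higher and 3 were neither, with a list median of -2.11 at percentile 0.06 of random lists. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34476663 to 34488393), a beta chain of the class II molecule, was 8.01-fold lower, with a log2 interval from -3.01 to -2.99. It was the gene with the most counts in the PBS DC library, at 4.92% of the total. H2-Eb1 was 3.85-fold lower, H2-Aa 3.17-fold lower and Cd74, the invariant chain that guides class II molecules, 5.49-fold lower. H2-DMb1, a part of the peptide-exchange molecule H2-DM, had a log2 ratio of -3.55. Ciita, the master regulator of class II transcription, had a log2 ratio of -0.10, and Ifi30, a lysosomal reductase, one of 0.78; both were named after their values were seen. Summed over the list, expression was 96919 CPM in the PBS library and 19831 CPM in the treated one. Against random lists not matched on expression the class II median lay at percentile 7.19, inside their range. After correction for gene length and GC content it was -1.42, still below the range.

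Of the 20 chemokine genes, 12 were higher, 1 was lower and 7 were neither, with a list median of 1.28 at percentile 98.5. Ccl6 (ENSMUSG00000018927, chromosome 11, 83478708 to 83483913) was 17.9-fold higher and had the most counts of the list. Ccl17, a ligand of CCR4 made by dendritic cells, was 11.4-fold higher, and Ccl2, which recruits monocytes through CCR2, was 2.63-fold higher. Cxcl10, a ligand of CXCR3, was 2.83-fold higher and Cxcl14 had a log2 ratio of -1.70. After correction for gene length and GC content the chemokine median lay at percentile 90.1, inside the range of random lists. Of the 22 glycolysis and hypoxia genes, 12 were lower, 4 were higher and 6 were neither, with a list median of -1.07 at percentile 2.34. Aldoa, Eno1, Pkm and Ldha, all enzymes of glycolysis or lactate formation, had log2 ratios of -2.37, -4.41, -1.99 and -1.91. Hk2, a hexokinase, was 36.0-fold higher and Vegfa, the angiogenic growth factor, had a log2 ratio of 2.61. The glycolysis call was lost with the list mean at percentile 8.14, with unmatched random lists at 18.8 and after the length and GC correction at 4.40.

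**Figure D1:**
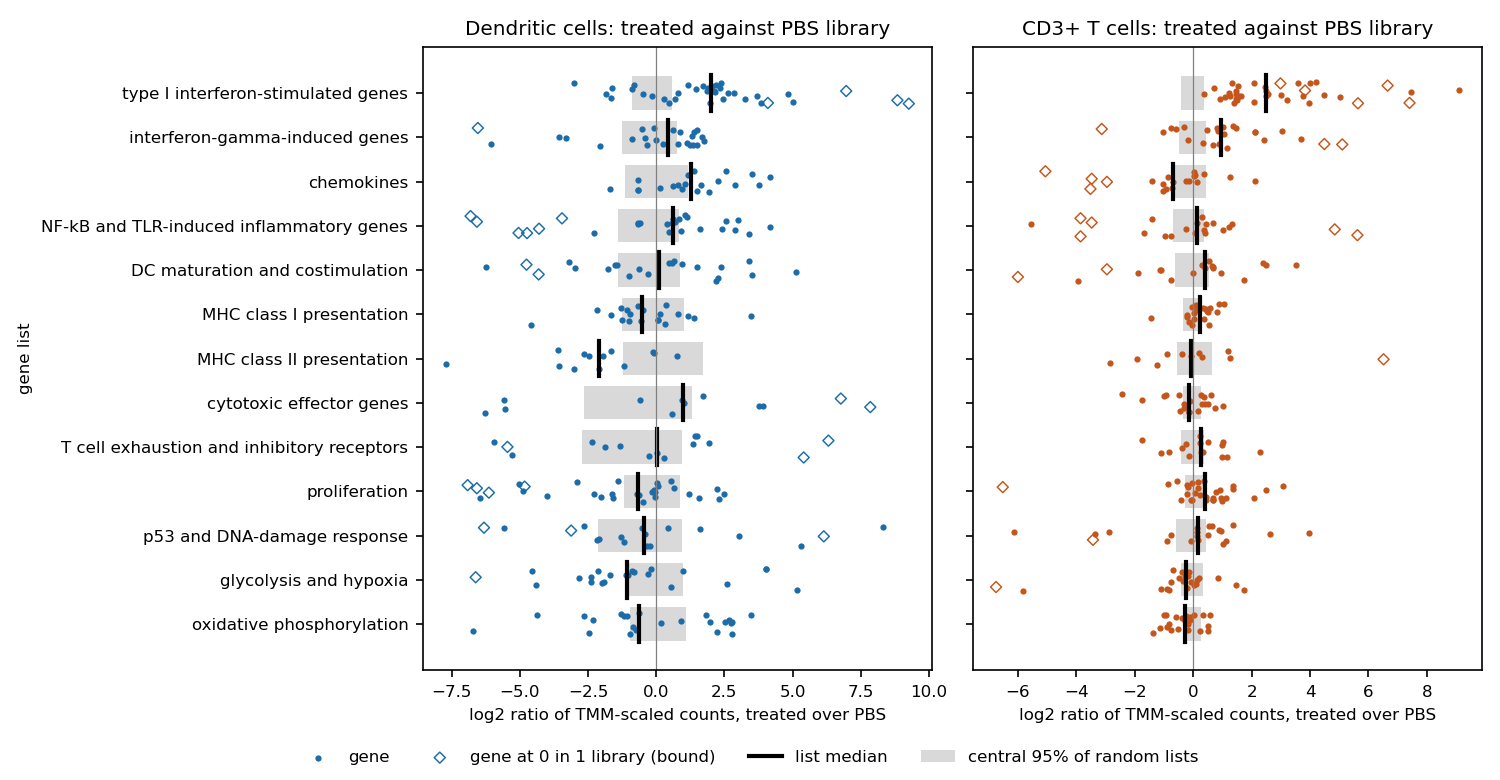
Log2 ratios (treated over PBS) of the measured genes of 13 programme lists, for the DC libraries on the left and the T cell libraries on the right; each point is a gene, open diamonds are genes at 0 in 1 library drawn at their bound, black bars are list medians and grey bars the central 95% of random lists. The interferon-stimulated genes lie to the right in both cell types, with medians of 4.01-fold and 5.58-fold, and the MHC class II genes lie to the left in DCs, with a median of -2.11.

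The list of DC maturation and costimulation genes had 7 members higher, 8 lower and 7 neither of 22, with a median of 0.08 at percentile 71.8. Cd86 (ENSMUSG00000022901, chromosome 16, 36424231 to 36486443), a costimulatory ligand of CD28, was 4.54-fold higher, with a log2 interval from 2.12 to 2.24. Its relative Cd80 had a log2 ratio of 0.58 and Cd40, the receptor for T cell help, one of 0.95. Cd83 and Ccr7, a marker of mature DCs and the receptor that guides DCs to lymph nodes, had log2 ratios of -1.52 and -1.77. The endosomal TLR pathway had 6 members higher, 7 lower and 4 neither of 17, with a median of 0.40 at percentile 77.3. Tlr7, an endosomal receptor for single-stranded RNA, was 5.89-fold higher, while Tlr8 had 285 counts in the PBS library and 1 in the treated one, a log2 ratio of -7.34 with an interval from -12.6 to -4.85. The list of NF-kB and TLR-induced inflammatory genes had 9 members higher, 7 lower and 10 neither of 26, with a median of 0.61 at percentile 94.2. Il1b, the most abundant member, had a log2 ratio of 0.47. Il12b, a subunit of IL-12 and IL-23, had 592 counts in the PBS library and 0 in the treated one, at least 112-fold lower. Interferon-gamma-induced genes had 9 members higher, 5 lower and 10 neither of 24, with a median of 0.44 at percentile 90.1. The means of these 4 lists were of the opposite sign to their medians, at -0.23 for maturation, -0.40 for the TLR pathway, -0.32 for inflammatory genes and -0.35 for interferon-gamma-induced genes.

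MHC class I presentation genes had 3 members higher, 7 lower and 10 neither of 20, with a median of -0.53 at percentile 21.5. B2m, the shared light chain of class I molecules, had a log2 ratio of 1.15 and H2-D1 one of -1.08. After the length and GC correction the class I median was 0.12. Immunosuppressive myeloid genes had 4 members higher, 6 lower and 2 neither of 12, with a median of -1.05 at percentile 12.6, and of 0.07 over the 9 with at least 20 counts in both libraries. Arg1, the arginine-degrading enzyme of suppressive myeloid cells, was 7.18-fold lower. Immediate-early and heat-shock genes had 6 members higher, 3 lower and 9 neither of 18, with a median of 0.51 at percentile 87.2 and a mean of 1.03 at 98.8, above the range of random lists, and the chaperone gene Hspa1b had a log2 ratio of 8.32. Proliferation genes had 5 members higher, 14 lower and 11 neither of 30, with a median of -0.66 at percentile 13.9 and a mean of -1.59 at percentile 1.69, but a median of -0.07 at percentile 28.8 over the 23 with at least 20 counts in both libraries. Genes of the p53 response had 5 members higher, 8 lower and 5 neither of 18, with a median of -0.46 at percentile 48.1. The p53 target Cdkn1a had a log2 ratio of -1.28.

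Oxidative phosphorylation genes had 9 members higher, 8 lower and 6 neither of 23, with a median of -0.64 at percentile 9.60, and of 0.04 after the length and GC correction. Cox6c and Ndufa1, small subunits of the respiratory chain, had log2 ratios of 3.47 and 2.77, while Uqcrc1 and Ndufa9 had ratios of -2.31 and -2.47. Cytotoxic effector genes had 6 members higher, 3 lower and 3 neither of 12, with a median of 0.98 at percentile 94.6. In the DC libraries Gzmb, a killer cell protease, had 0 counts with PBS and 391 with treatment. At the floor of 3 counts it was 230-fold higher, with an interval from 186-fold upward. Ifng, also at 0 with PBS, was 109-fold higher at that floor, with an interval from 87.6-fold upward. T cell activation genes had a median of 0.47 and a mean of -0.28 over 13 genes, with 5 higher, 5 lower and 3 neither. Genes of T cell exhaustion and inhibitory receptors had a median of 0.01 and a mean of -0.29 over 15 genes, with 6 higher, 6 lower and 3 neither. Pdcd1, which encodes PD-1, had a log2 ratio of 1.35. Naive and memory genes had a median of -1.63 over 8 genes, with 2 higher and 5 lower, and of -0.15 over the 4 with at least 20 counts in both libraries. Regulatory T cell genes had a median of -0.53 over 12 genes, with 5 higher and 6 lower, and of 0.79 over the 8 with at least 20 counts in both libraries. Th1 genes had a median of 1.03 over 10 genes, with 6 higher and 3 lower. These 5 T cell lists lay at percentiles 82.3, 76.9, 37.7, 51.8 and 93.5. The Th2 and Th17 lists had too few measured members for a percentile, with Il1rl1 at a log2 ratio of 2.56 and both Th17 members lower at a median of -3.68.

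Markers of other cells were read in the same libraries, and single marker genes were chosen after their values were seen. Macrophage markers were lower, with 8 lower, 0 higher and 7 neither of 15 and a median of -1.31 at percentile 1.96, moving with the class II and glycolysis genes. After the length and GC correction the macrophage median was -0.98 at percentile 2.92, inside the range of random lists. The marker sum was 21420 CPM in the PBS library and 6506 CPM in the treated one. C1qc, a complement component of tissue macrophages, had a log2 ratio of -3.18, while the macrophage markers Adgre1 and Csf1r had ratios of 0.27 and 0.25. T cell markers had a median of -5.49 at percentile 0.26, but members differed in direction, with Cd3g from 576 to 1 count and Cd5 from 1 to 278. NK cell markers had a median of 3.04 at percentile 99.0 over 5 genes, 4 higher and 1 lower, the direction of Gzmb and Ifng in these libraries. The sum of cDC markers fell from 58896 to 8279 CPM, mostly through H2-Ab1 and Cd74, while Zbtb46 and Flt3, a transcription factor and a growth factor receptor of cDCs, had only 0.37 and 0.66 CPM in the PBS library. Markers of cDCs had a median of 0.79 over 8 genes, 3 higher and 2 lower, of cDC1 0.90 over 11 genes, 5 higher and 3 lower, and of cDC2 0.53 over 10 genes, 4 higher and 4 lower. The means of cDC1 and cDC2 markers were -0.34 and -0.19. Clec9a, a cDC1 receptor for dead cells, had a log2 ratio of 3.45, and Cd209a, a lectin of cDC2, one of -4.02. Markers of mature regulatory DCs had a median of -0.28, of plasmacytoid DCs -1.11, of monocytes 0.36, of neutrophils 1.46, of fibroblasts -0.34 and of plasma cells -3.14. Over genes with at least 20 counts in both libraries, the medians were 0.08 for mature regulatory DC and 0.97 for fibroblast markers. In that setting plasmacytoid DC markers had a median of 1.13 over 3 genes and T cell markers 1.68 over 2, too few for a percentile. The 9 lists from cDCs onward lay inside the range of random lists.

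Lists with too few measured members for a percentile in DCs were CD8 T cells with a median of 0.56, CD4 T cells with -3.71, B cells with -1.66, mast cells with 0.79, MC38 epithelial cells with -5.37, endothelial cells with -1.27 and erythroid cells with 0.50. No gamma-delta T cell marker was measured in either cell type. RNA content also differed between the DC libraries. All 12 measured mitochondrially encoded genes were higher in the treated library, with a median of 3.21. Of 80 cytosolic ribosomal protein genes, 50 were higher and 2 lower, with a median of 1.78. These 2 families were chosen after their values were seen. Ribosomal protein genes took 3.61% of counts in the PBS DC library and 9.74% in the treated one. Of 7857 genes with at least 100 counts in the PBS DC library, 942 had 0 counts in the treated one, and in the reverse direction 213 of 6476 genes did. The genes furthest apart were of this kind: of the treated-high genes, Ifi44 and Xpnpep3 went from 0 to 1040 and 789 counts, and of the treated-low genes, Yif1b and Lat2 went from 3272 and 3228 counts to 0, as did the interferon-inducible Ifi27 from 2380.

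**Figure D2:**
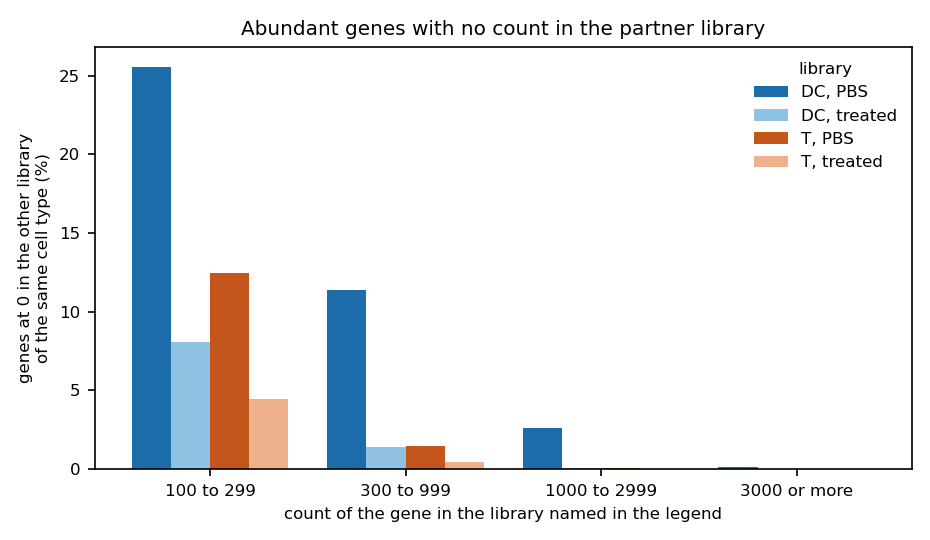
Percent of genes with 0 counts in the partner library, by count range in the library named, for the 4 libraries; each bar covers all genes in that count range. For genes of the lowest range shown the share was 25.5% for the PBS DC library and 4.46% for the treated T cell library.

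The comparison within T cells addresses how the treatment affected T cells in the tumour. Type I interferon-stimulated genes were higher in the treated T cell library, with a median log2 ratio of 2.48 (5.58-fold) over 37 genes and of 1.60 over the 28 with at least 20 counts in both libraries, and interferon-gamma-induced genes were higher by a median of 1.93-fold over 24 genes. Proliferation genes had a median ratio of 1.32-fold over 30 genes, of which 6 were called higher. In the order given, these list calls held in 12, 12 and 10 of 12 alternatives. As in DCs, the alternatives of scaling alone could not change these calls. Of 20 cytotoxic effector genes 1 was called higher and 3 lower: Gzma was 2.02-fold higher, and Gzmd, Gzme and Gzmf were lower, while Gzmb and Ifng had ratios of 1.33-fold and 1.68-fold. Cd69, an early activation marker, was 2.93-fold higher and Cdkn1a, a p53 target that arrests the cell cycle, 6.15-fold higher. Among 11058 genes that passed the filter, 2025 were called higher and 2805 lower. Of the lower genes 873 were at 0 in the treated library, and of the higher ones 276 were at 0 in the PBS library. Of 20 lists, 4 lay outside the range of random lists, where randomly drawn genes give 1. As in DCs, members that vary together can put more lists outside by chance.

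Of the 37 interferon-stimulated genes, 34 were higher, 0 were lower and 3 were neither in the treated T cell library. The list median was 2.48, with a bootstrap interval from 1.55 to 3.59, at percentile 100 of random lists. Zbp1 (ENSMUSG00000027514, chromosome 2, 173048405 to 173060716), the most abundant member, was 2.51-fold higher, and Irf9, the DNA-binding part of the interferon-activated complex, was 2.92-fold higher. Irf7 was 4.26-fold higher, from 65.8 to 280 CPM. Ifit3 was 9.20-fold higher, with a log2 interval from 3.05 to 3.35. Usp18, a brake on interferon signalling, was 22.3-fold higher and Mx1 32.9-fold higher. Oasl1 had 0 counts in the PBS library and 513 in the treated one. At the floor of 3 counts it was 169-fold higher, with an interval from 137-fold upward. Stat2 and Rsad2, named after their values were seen, were among the members not called, with log2 ratios of 0.37 and 0.91. Summed over the list, expression was 907 CPM in the PBS library and 3264 CPM in the treated one.

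Of the 24 interferon-gamma-induced genes, 12 were higher, 2 were lower and 10 were neither, with a median of 0.95 at percentile 99.99. Igtp, an interferon-inducible GTPase, was 4.35-fold higher and Cxcl10 was 4.36-fold higher. The abundant members Serpina3g and Gbp4 had log2 ratios of 0.47 and -0.60. MHC class I genes had 1 member higher, 1 lower and 18 neither of 20, with a median of 0.23 at percentile 96.3. H2-K1 and H2-D1, which present peptides to CD8+ T cells, had log2 ratios of 0.43 and 0.38. Nlrc5, the regulator of class I transcription, had a log2 ratio of 1.05 and Erap1, which trims peptides, one of -1.44.

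Cytotoxic effector genes had 1 member higher, 3 lower and 16 neither of 20, with a median of -0.13 at percentile 23.8, and of 0.03 after the length and GC correction. Nkg7, a granule protein and the gene with the most counts in both T cell libraries, had a log2 ratio of -0.30, and Prf1, the pore-forming perforin, one of 0.29. Gzma was 2.02-fold higher, whereas Gzmd, Gzme and Gzmf had log2 ratios of -1.01, -2.42 and -1.74. T cell activation genes had 3 members higher, 1 lower and 11 neither of 15, with a median of 0.33 at percentile 97.3. Cd28 had a log2 ratio of 1.05 and Cd38 one of -2.64. Il2, the T cell growth factor, went from 3 to 199 counts, a log2 ratio of 6.04 with an interval from 4.47 to 8.33. Genes of exhaustion and inhibitory receptors had 4 members higher, 2 lower and 10 neither of 16, with a median of 0.26 at percentile 92.2. Pdcd1 and Lag3, inhibitory receptors, had log2 ratios of 0.24 and -0.38, Nr4a1 one of 1.03 and Tox, a transcription factor of exhausted cells, one of -1.75.

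Naive and memory genes had 1 member higher, 2 lower and 10 neither of 13, with a median of 0.36 at percentile 90.1 and a mean of -0.10. Tcf7, a transcription factor of stem-like T cells, had a log2 ratio of 1.34. Regulatory T cell genes had 1 member higher, 5 lower and 8 neither of 14, with a median of -0.11 at percentile 47.1 and a mean of -1.10, and the median was 0.07 over the 12 with at least 20 counts in both libraries. Foxp3, the lineage factor of regulatory T cells, had 99 counts in the PBS library and 0 in the treated one. At the floor of 3 counts it was 33.3-fold lower, with an interval from 26.6-fold upward. Ikzf2 had a log2 ratio of -2.70. Th1 genes had 0 members called of 10, with a median of 0.40 at percentile 93.6. The Th2 and Th17 lists had 2 measured members each and no percentile, with medians of -0.58 and -4.38. Cd8a had 46523 and 47563 counts, a log2 ratio of 0.02, and Cd4 had 17 and 252 counts, a log2 ratio of 3.88 with an interval from 3.17 to 4.68.

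Proliferation genes had 6 members higher, 1 lower and 23 neither of 30, with a median of 0.40 at percentile 98.0. Top2a, the replication topoisomerase, had a log2 ratio of 1.38, Aurka and Tpx2, a mitotic kinase and its activator, were 5.65-fold and 8.47-fold higher, and Kif20a went from 272 to 0 counts. The call was lost with the list mean at percentile 90.0 and after the length and GC correction at 95.3. Genes of the p53 response had 5 members higher, 4 lower and 12 neither of 21, with a median of 0.16 at percentile 77.4 and a mean of -0.16. The members higher were Cdkn1a (ENSMUSG00000023067, chromosome 17, 29309950 to 29319701), Mdm2, Btg2, Zmat3 and Trp53inp1, with log2 ratios of 2.62, 1.35, 1.04, 3.98 and 1.12. Sesn1 had a log2 ratio of -2.87.

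Chemokine genes had 2 members higher, 7 lower and 11 neither of 20, with a median of -0.70 at percentile 2.30. Ccl5 and Ccl4, the most abundant, had log2 ratios of -0.14 and 0.12, while Cxcl2, which attracts neutrophils, had one of -1.42. The chemokine call was lost in 6 of 12 alternatives, with a percentile of 22.8 when at least 100 counts were asked for and 11.4 for the list mean. Among the alternatives that kept it were those of scaling alone, which could not change its percentile. Its median was -0.20 over genes with at least 20 counts in both libraries and -0.38 after the length and GC correction. Inflammatory NF-kB and TLR-induced genes had 5 members higher, 6 lower and 10 neither of 21, with a median of 0.12 at percentile 78.8 and a mean of -0.26. Nfkbia, an inhibitor of NF-kB, had a log2 ratio of 1.23. The endosomal TLR pathway had 4 members higher, 3 lower and 7 neither of 14, with a median of 0.33 at percentile 87.9, and of 0.87 at 99.6 over the 12 with at least 20 counts in both libraries, and Tlr7 had a log2 ratio of -3.27. Maturation and costimulation genes had 4 members higher, 6 lower and 9 neither of 19, with a median of 0.42 and a mean of -0.18 at percentile 93.5 for the median. Cd80 was 5.29-fold higher and Cd86 2.17-fold lower.

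MHC class II genes had 3 members higher, 3 lower and 5 neither of 11, with a median of -0.08 at percentile 33.6 and a mean of 0.19. Glycolysis and hypoxia genes had 2 members higher, 3 lower and 17 neither of 22, with a median of -0.25 at percentile 13.1, and Aldoa had a log2 ratio of 0.12. Oxidative phosphorylation genes had 0 members higher, 3 lower and 20 neither of 23, with a median of -0.28 at percentile 2.78. Immediate-early and heat-shock genes had 4 members higher, 0 lower and 14 neither of 18, with a median of 0.20 at percentile 86.8, and Klf6 had a log2 ratio of 1.21. Immunosuppressive myeloid genes had 2 members higher, 5 lower and 4 neither of 11, with a median of -0.87 at percentile 9.41. Of the T cell lists inside the range, the endosomal TLR pathway and oxidative phosphorylation lay outside it in 3 of 12 alternatives each, and maturation, class I and Th1 genes in 1 each.

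T cell markers had 0 members called of 12, with a median of 0.22 at percentile 91.4, and CD8 T cell markers had a median of 0.34 over 5 genes. CD4 T cell markers had a median of -0.59 and NK cell markers one of -0.41. Macrophage markers had 1 member higher, 5 lower and 8 neither of 14, with a median of -0.36 at percentile 16.1. Monocyte markers had 2 members higher and 2 lower of 9, with a median of 0.48, which lay just above the range of random lists, and a mean of -0.31. Fibroblast markers had 1 member higher, 6 lower and 4 neither of 11, with a median of -2.74 at percentile 0.295, and the median was -0.43 and inside the range among genes with at least 20 counts in both libraries. Medians were -0.04 for cDC, -1.64 for cDC1, 0.34 for cDC2, 0.02 for mature regulatory DC, -0.54 for plasmacytoid DC and 0.50 for erythroid markers, all inside the range. The means of cDC2 and mature regulatory DC markers were -0.04 and -1.09. Lists with too few members had medians of -0.45 for B cells, 0.60 for plasma cells, -0.18 for neutrophils, -6.64 for mast cells, -3.08 for MC38 epithelial cells and -2.82 for endothelial cells. Of 8607 genes with at least 100 counts in the PBS T cell library, 342 (3.97%) had 0 counts in the treated one. The genes furthest apart were again at 0 to 4 counts in 1 library, among them Rassf7 from 0 to 893, Phf11c from 4 to 1846 and Asah1 from 1163 to 0.

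The comparison of the cell types asks whether the DC and T cell libraries differed from their PBS partners in the same genes. Interferon-stimulated genes were the shared group: of 36 present in both tables, 22 were called higher in both cell types, and Ifi35, Cmpk2, Oas1a and Oas1g were higher in T cells and lower in DCs. The chemokine list lay above the range of random lists in DCs and below it in T cells, and the class II and glycolysis lists lay outside the range in DCs only; these differences between cell types were not tested. Across 9388 genes the DC and T cell log2 ratios had a Spearman's rho of -0.0178 and a Pearson's r of 0.00439, over genes, which are not independent replicates. Genes higher in both numbered 508, where independence gives 447, and genes lower in both numbered 878, where it gives 837. Genes higher in DCs and lower in T cells numbered 694, where independence gives 596, and genes lower in DCs and higher in T cells 633, where it gives 627.

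**Figure D3:**
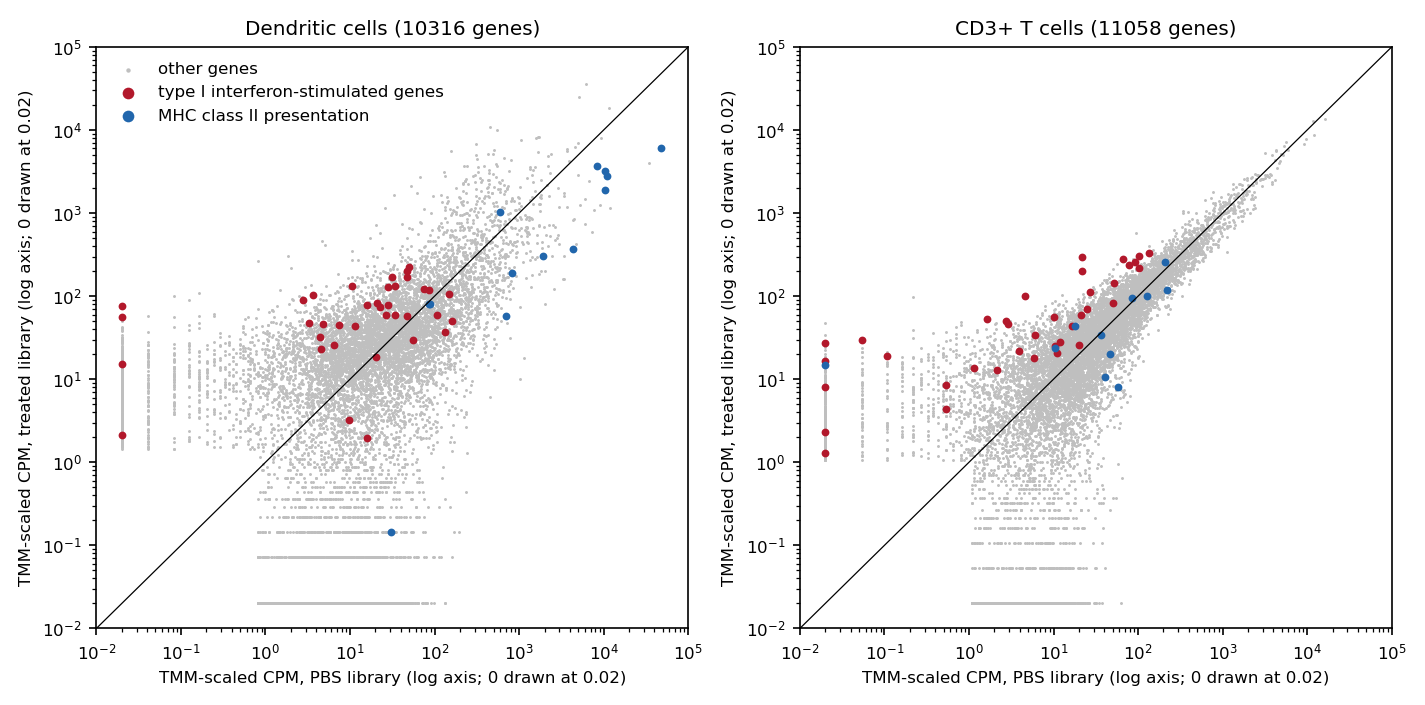
Expression in the treated library against the PBS library in TMM-scaled CPM on log axes, DCs on the left and T cells on the right; each grey point is a gene, interferon-stimulated genes are red, MHC class II genes are blue and genes at 0 are drawn at 0.02 CPM. Across genes the log2 CPM values had a Pearson's r of 0.602 in DCs and 0.819 in T cells.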

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

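Of the tests in this part, the test of chance loss, the length and GC correction and the requirement of counts in both libraries were chosen only after the result was seen. The results listed here are the lists, the genes furthest apart, the genes fixed in advance and the other genes named in the text for which the DC log2 ratio and the T cell log2 ratio lay in opposite directions beyond the set limits. Across all genes, 694 were higher in DCs and lower in T cells and 633 the reverse. None of these differences between cell types was tested, since each rests on 1 library per group.

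The chemokine list had a median of 1.28 in DCs and -0.70 in T cells, a difference of -1.99 (T cells minus DCs). After the length and GC correction both lay inside the range of random lists, at 0.82 and -0.38, and the T cell median was -0.20 over genes with at least 20 counts in both libraries. Cd86 had log2 ratios of 2.18 and -1.12, a difference of -3.30. Tlr7 had ratios of 2.56 and -3.27, a difference of -5.83. The next genes were among those furthest apart in 1 cell type, each at 0 to 4 counts in at least 1 library. All but Phf11c were at 0 in a library of the cell type where they were furthest apart. That ratio and the difference are therefore bounds set by the floor of 3 counts, and the interval limit of the ratio lies nearer 0. The ratio in the other cell type is a bound only where a library there was also at 0. BC035044 had ratios of 8.65 in DCs and -5.44 in T cells, a difference of -14.09, and Supt16 had 8.39 and -3.45, a difference of -11.85. Rassf7 had -4.43 and 8.20, a difference of 12.63. Phf11c had -6.15 and 8.84, a difference of 14.98, and Prkra had -5.71 and 7.36, a difference of 13.07. Tmem176b had -2.42 and 6.95, a difference of 9.37. Pkd1l3 had -3.35 and 6.83, a difference of 10.18, and B4galt4 had -3.27 and 6.71, a difference of 9.98. Cep19 had 1.94 and -7.62, a difference of -9.56. Cass4 had 1.78 and -7.55, a difference of -9.33.

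Genes of the fixed lists that lay in opposite directions are given here with the DC ratio before the T cell ratio; for Ccl17, Cmpk2, Oas1g, Zbtb46 and Flt3, at 0 in a T cell library, the T cell ratio and the difference are bounds. Ccl17 had 3.51 and -2.95, a difference of -6.46, and Cxcl2 had 1.06 and -1.42, a difference of -2.48. Cd209a had -4.02 and 4.95, a difference of 8.98. Cdkn1a had -1.28 and 2.62, a difference of 3.90. Of the interferon-stimulated genes, Cmpk2 had -1.61 and 3.83, a difference of 5.44, and Ifi35 had -1.66 and 1.51, a difference of 3.17. Oas1a had -1.84 and 4.20, a difference of 6.05, and Oas1g had -3.03 and 2.99, a difference of 6.02. Ikzf2 had 1.15 and -2.70, a difference of -3.85, and Il1rl1 had 2.56 and -1.77, a difference of -4.33. Ndufa1 had 2.77 and -1.15, a difference of -3.92, and Vegfa had 2.61 and -5.82, a difference of -8.43. The marker genes Zbtb46 and Flt3 had 3.48 and -5.33, a difference of -8.82, and 2.93 and -3.01, a difference of -5.94.

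Genes that were abundant in the PBS DC library and at 0 in the treated one numbered 942 of 7857. Shallower sequencing alone is argued against by the depths: at the treated total, 100 counts in the PBS library correspond to 59.1 counts. Thinning the PBS library to that total left 0 of these genes at 0. That outcome was fixed by the depths and adds nothing to them. A change in cell types present stays open: 11 of 100 marker genes (11%, interval 5.62% to 18.8%) were at 0, against 10.2% for other genes of like count. Transcripts lost by chance from a low-input library may account for part of them, as 213 genes with at least 100 counts in the treated library were at 0 in the deeper PBS library. An effect of the treatment on these genes was not tested and remains open.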

How the results depend on the processing

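Of the tests in this part, centring, the requirement of counts in both libraries, and the length and GC correction were chosen only after the result was seen. Among 71 values of gene counts, list counts and the correlation across alternatives, 65 stayed on the same side and within the set limits, 5 moved and 1 reversed. For the lists that lay outside the range, all 96 medians under alternatives kept their direction. Alternatives of scaling alone shift all genes alike by little, so they tested direction only weakly. Keeping a direction is also less than keeping the call. The call held in 6 of 12 alternatives for T cell chemokines and in 9 of 12 for DC glycolysis and hypoxia. Of 2075 values of named genes, 1810 stayed within their counting interval, 265 moved and 0 reversed. At a 4-fold threshold, 1922 DC genes were higher and 3295 lower, and in T cells 1003 were higher and 1774 lower; the stricter threshold itself lowers these counts. DC lists outside the range numbered 2 with unmatched random lists and 2 after the length and GC correction, against 4; the cause was not tested. The rho between DC and T cell ratios was 0.025 over the 2713 genes at least 2-fold apart in both, against -0.0178; the cause was not tested. Centring moved the DC median of all genes from -0.36 to 0, with 3617 genes higher and 3911 lower against 3112 and 4317. It brings these numbers closer by construction, so it shows only that the size of the excess varies with where 0 is set. Total-count, DESeq2 and upper-quartile scaling, which lay close together, kept the excess, with 3044, 3080 and 3185 DC genes higher and 4385, 4347 and 4262 lower. In the main setting 1525 of the lower DC genes were at 0 in the treated library. Of the higher ones, 387 were at 0 in the PBS library. Much of the excess of lower genes thus lay in genes with no count in 1 library. Upper-quartile scaling moved the T cell median from -0.07 to -0.17.

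No paired analysis was possible because by the labels each group has 1 library, and for the same reason no replicate was left out. The further PBS library of each table, which matched no sample, was not used. Comparison columns by the authors were not used here. The FPKM alternative equals total-count scaling, as its length term cancels in a ratio. Depth limits values for genes at 0, where a library allows up to 3 counts.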

Other observations

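Of the tests in this part, those of chance loss and of macrophage and monocyte content, the single marker genes, the length and GC correction, the gene families and the scan of gene ontology terms were chosen only after the result was seen.

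Gene families outside the fixed lists also differed between the libraries, and their directions held under every scaling computed (TMM, total counts, DESeq2, upper quartile, TMM without ribosomal, mitochondrial and receptor genes, and totals without the 50 most abundant genes). These scalings lay close together and shift all genes alike: the DC median of cytosolic ribosomal protein genes ran only from 1.69 to 1.83. In T cells, 21 of 82 cytosolic ribosomal protein genes were lower and 1 was higher in the treated library, with a median of -0.75, whereas the same family had a median of 1.78 in DCs. Subunits of NADH dehydrogenase, cytochrome c oxidase and ATP synthase with a listed length under 1000 bases had a median of -0.81 in T cells and 1.75 in DCs, over 21 genes each, while the fixed list of oxidative phosphorylation had medians of -0.28 and -0.64. With DC genes split by length into 4 groups of like size, the shortest had a median of -0.93 and the longest one of 0.37.

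In a scan of gene ontology terms listed with the genes, 933 terms of 20 to 200 genes were read in T cells. Of these, 41 lay above and 34 below the range of 1000 random lists, where randomly drawn genes give 23.3 each way. Genes of a term can vary together and terms share genes, so more terms than this can lie outside by chance. Cellular response to interferon-beta had a median of 1.02, with 24 of 46 genes higher and 1 lower. Negative regulation of viral genome replication had a median of 0.98 over 42 genes, and cytoplasmic translation one of -0.74 over 81. In DCs, 92 of 885 terms lay above and 35 below, where randomly drawn genes give 22.1 each way, with the same limit. Cytoplasmic translation had a median of 1.60 and glycolytic process one of -1.99, with 17 of 25 genes lower and 4 higher. Sterol biosynthetic process, which makes cholesterol precursors, had a median of -1.80, with 15 of 26 genes lower and 4 higher. The named terms were not those furthest from random lists in DCs. Those were sensory perception of smell, with a median of 1.27 over 24 genes, and nucleotide metabolic process, with -2.79 over 20. In T cells the furthest term was embryonic digit morphogenesis, with a median of -2.23 over 29 genes.

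Interferon-stimulated genes were higher in the treated T cell library. Chance loss of transcripts is argued against, since over the 28 members with at least 20 counts in both libraries the median was 1.60 at percentile 100, and a length and GC trend is argued against, since the corrected median stayed at percentile 100. An increase in macrophages as large as the interferon rise is argued against in the treated T cell preparation. Macrophage markers had a median of -0.36 (interval over members -1.12 to 0.37), far below the interferon list. That interval spans 0, so a smaller increase stays open. These markers do not show which cells the interferon transcripts came from. The most abundant macrophage markers, Spp1 and Arg1, had log2 ratios of -0.51 and 0.48. Macrophage markers summed to 940 CPM in the PBS T cell library and 885 CPM in the treated one, so the CD3+ label does not settle carry-over. Of this marker list, Arg1, Mrc1, Spp1 and Trem2 are also in the immunosuppressive myeloid list. More monocytes in that preparation stay open: monocyte markers had a median of 0.48 (interval -1.92 to 1.03), with members going both ways and several of them also made by T cells. Of the 9 monocyte markers, 6 had a log2 ratio above 0, and their sum was 3477 CPM in the PBS T cell library and 5563 CPM in the treated one. The monocyte median lay at percentile 98.8 over the 8 with at least 20 counts in both libraries, and at 97.9 after the length and GC correction. Markers going the other way included Vcan and F13a1, with log2 ratios of -1.92 and -4.84. A response of the T cells to interferon after treatment is a candidate explanation that these data did not test, with 1 library per group.

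MHC class II genes were lower in the treated DC library. A length and GC trend as the whole cause is argued against, as the corrected median lay at percentile 0.240, but part of the drop went with that trend, since the median was -2.11 before and -1.42 after the correction. A few genes taking most counts is argued against by their shares. The 50 most abundant genes of each library took 32.7% of counts in the PBS DC library and 30.7% in the treated one. With such genes left out of the scaling the class II median was -2.20 (interval -3.09 to -1.28). That step shifts all genes alike and moved the treated over PBS scaling ratio only from 0.567 to 0.603, so it adds little. Fewer macrophages in the treated preparation may contribute and stays open: macrophage markers had a median of -1.31 (interval -2.31 to 0.07) and one of -0.98 inside the range of random lists after the length and GC correction, and their most abundant members, Arg1 and Spp1, had log2 ratios of -2.84 and -0.79. The gate used to isolate DCs is not given in the sources used here. An effect of the treatment on class II expression by DCs remains an untested hypothesis.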
